A study of Drosophila melanogaster with 14 samples.

How the data were processed

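Ovaries of adult Drosophila melanogaster aged 3 to 14 days were the tissue in every library. The series lists 14 samples, of which 8 had processed files and were analysed here. The other 6, which are 2 libraries of RNA polymerase II chromatin immunoprecipitation, their 2 inputs and 2 small RNA libraries, were not analysed here. Cutoff (gene cuff), a nuclear protein needed for piRNA production in the germline, was knocked down with a short hairpin RNA driven by the germline driver nos-GAL4 (shCuff). The control for total and poly(A) RNA carried the same driver with a hairpin against the eye colour gene white (shWhite). The control for nuclear run-on carried the driver without a hairpin, so that comparison differs from the others in its control genotype. Total RNA was depleted of ribosomal RNA, poly(A) RNA was selected on beads, and in nuclear run-on the RNA extended by engaged polymerases in isolated nuclei took up bromo-UTP and was captured with an antibody, per the labels' protocols.

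Each deposited file covered the dm3 genome in 168744 bins of 1 kb, 15 of them shorter because they end a sequence, with no gene names. The submitters' processing notes name cutadapt and Bowtie 0.12.7 with the dm3 build; read filters and the tool that counted reads are not given in the sources used here. Column 6 of each deposited file held the count of reads per bin; these counts were whole numbers in the 4 libraries of the first set (AC in the titles: replicate 1 of total RNA, and poly(A) RNA). In the 4 libraries of the second set (ES in the titles: replicate 2 of total RNA, and run-on) 1 to 8 bins were not whole, so those deposited values were treated as estimated counts and rounded to whole reads. Column 5 held the authors' RPKM, reads per kb and per 1000000 reads, and it summed to 999954 to 1000000 in each file. A directional kit was used, per the labels' protocols, but the deposited counts carry no strand, so sense and antisense reads could not be told apart. Reads from repeated sequence were placed by the authors under rules not given in the sources used here, which limits every value for piRNA clusters and heterochromatin. The names of the deposited files hold a code that differs between the first and the second set and another that both share. These may be Bowtie limits on mismatches and on the number of places where a read matches, which the labels do not state. If so, the sets differ in the mismatches allowed, and values of the first set cannot be compared freely with those of the second, above all in repeated sequence.

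The groups, the cluster positions, the design and most alternatives were fixed before the data were examined. The 7 piRNA clusters (loci whose transcripts are processed into PIWI-interacting RNAs) were 42AB, 38C_a, 38C_b, 80F and a cluster of chromosome 4 from 1258001 to 1349000, which are dual-strand, and 20A and flamenco, which are uni-strand. Their dm3 positions, rounded to kb, came from background knowledge of published cluster positions, with 50-kb flanks of 42AB and 38C and about 20 kb at 5 arm ends added. Chromosome arm names are those of the files: U and Uextra hold unplaced sequence, and 2RHet, 3LHet, 3RHet and the like hold heterochromatic scaffolds. No dm3 annotation was used here, so the planned gene-level test and the planned lists of genes were not computed, and the level of cuff was not analysed here.

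The planned test of total RNA was limma on log2(RPKM + 1). As the files hold counts, the test used was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, scaled to each library's total reads, and limma 3.58.1 with pseudocounts of 1 and 0.1 RPKM became an alternative. The model had a term for genotype and one for library set, leaving 1 residual degree of freedom over 4 libraries. Bins with a mean of at least 1 RPKM entered the bin test. Clusters, flanks and arm ends were tested together with 10-kb windows of the rest of the genome. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, over all features tested and, for the 7 clusters, over the list alone. Sets of cluster bins were also tested with camera, with a preset correlation of 0.01 and with an estimated one. Chromosome classes were tested in the same way together with the windows.

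The replicate block is the library set, AC or ES, which stands in the sample titles next to a running library number. Deviations from the group means of libraries in the same set correlated at 0.587 over 27388 bins; with 2 libraries per group this value says only that libraries of a set moved together. Without the block edgeR's test called 0 bins. Nothing in the labels says that replicates came from separate groups of flies, so p-values measure only the spread between these libraries, which may be technical.

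Poly(A) RNA and run-on had 1 library per group and no test. For these, and for each total RNA pair alone, the ratio of RPM (reads per 1000000 library reads) is given with a 95% exact conditional (Clopper-Pearson) interval. Intervals and limits from a count of 0, which is taken as 3 reads, cover counting error only, because reads copied by PCR are not independent molecules. Bins were counted as 2-fold higher or lower on the log2(RPKM + 1) scale, which understates the change of weakly covered bins. The median change of a cluster's bins was ranked among 10000 random bin sets of the same size matched on mean RPKM, and as an alternative the cluster's ratio was ranked among 10000 contiguous windows of the same length, with reads in each library and a mean RPM within 2-fold of the cluster's. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

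The edgeR step was tested on simulated counts with the real means, a dispersion of 0.1 in every library and 200 changed features. The changed features were drawn only from those above a minimum mean count, so recovery of weakly covered features is not described. Among 27388 bins the test recovered 31% of those changed 4-fold and 0% of those changed 2-fold, with 1 false call. Among 4340 windows and regions it recovered 73% and 8%, with 2 false calls. The biological coefficient of variation in the real data was 0.589 for bins and 0.326 for windows and regions, so the recovery for bins describes a cleaner experiment than this one. Counting intervals covered a true ratio of 0.5 in 98.4%, 95.5% and 94.6% of simulations at means of 5, 50 and 500 reads.

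The alternatives were limma with both pseudocounts, TMM factors, no filter on low values, no term for library set, the median over a cluster's bins, bins in place of windows as companions, each pair alone, median-ratio scaling and totals without mitochondrial reads. Those added after the data were seen were DESeq2 1.42.0, each library left out, totals without the most abundant bin, clusters without 1 bin and other fold thresholds of the scan described below. Regions named are all clusters, flanks and arm ends. For bins, the rule was the 10 largest changes each way among those past the threshold with the same sign in both pairs. Of these, 2 each way are printed because the files pair bins with no gene. They are the bin with the largest log2 change and the bin with the lowest p in edgeR's test.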

Results

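The data were 8 sequencing libraries of Drosophila ovaries. Total RNA was measured in 2 shWhite and 2 shCuff libraries, poly(A) RNA in 1 of each, and nuclear run-on in 1 shCuff library and 1 control library that carried the driver alone. The first set held 3357617 reads for shWhite replicate 1 and 2950394 for shCuff replicate 1 of total RNA, and 8366673 for shWhite and 10932667 for shCuff of poly(A) RNA. In the second set, total RNA had 5688670 reads for shWhite replicate 2 and 7344632 for shCuff replicate 2, and run-on had 2511887 for shCuff and 2438627 for the control. Reads lay in 20.01% to 27.0% of bins in the RNA libraries and in 41.8% and 42.2% in the run-on libraries. A bin of the unplaced sequence U, from 5301001 to 5302000, took 5.30% to 10.4% of the reads in the 4 libraries of the first set but 1.51% in shWhite replicate 2 and 0.128% in shCuff replicate 2. The libraries also differed in how reads were spread. Of the bins with reads, 8.37% held 1 to 3 reads in shCuff replicate 2, against 44.4% in shWhite replicate 1, 40.3% in shCuff replicate 1 and 35.7% in shWhite replicate 2.

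**Figure D1:**
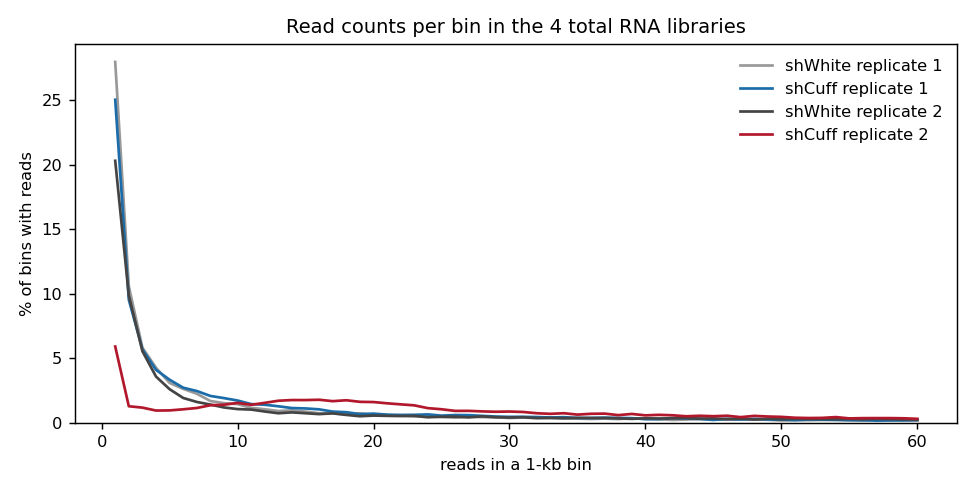
Share of bins with reads (y axis, %) that hold a given number of reads (x axis, reads in a 1-kb bin) in the 4 total RNA libraries, 1 line per library. The line of shCuff replicate 2 has a lower peak at 1 read, which holds 5.91% of its bins with reads against 20.3% to 28.0% in the other 3 libraries. It has a second maximum at 16 reads, with 1.79% of its bins with reads.

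The main question of the design was whether transcripts of piRNA clusters depend on Cutoff, as the series title puts it. In total RNA, the dual-strand cluster 42AB, a major source of germline piRNAs on 2R from 2144001 to 2387000, fell from 437.5 to 46.8 RPM (reads per 1000000 library reads) in the replicate 1 pair and from 182.6 to 34.7 in the replicate 2 pair. The dual-strand cluster 38C_b on 2L from 20148001 to 20228000 fell from 73.3 to 8.81 and from 30.1 to 5.72. The uni-strand cluster 20A on X from 21392001 to 21432000 also fell, from 271.9 to 155.6 and from 181.6 to 47.4. The dual-strand cluster of chromosome 4, from 1258001 to 1349000, rose from 13.7 to 39.0 and from 8.61 to 30.4. Thus 3 of the 7 clusters fell and 1 rose, with p-values adjusted over the list alone, and the other 3 did not pass. Among contiguous windows of the same length and similar coverage, the ratios of the replicate 1 and replicate 2 pairs lay at percentiles 0 and 0.56 for 42AB, 0 and 0.21 for 38C_b, and 0.72 and 1.61 for 20A. For the chromosome 4 cluster they lay at 90.67 and 46.93. In the replicate 2 pair the median log2 ratio of such windows was 1.92, against 1.82 for that cluster, so its rise in this pair did not exceed that of windows with similar coverage. Among random bin sets matched on mean RPKM, its 6 bins with at least 1 RPKM lay at percentiles 99.99 and 98.04 in the replicate 1 and replicate 2 pairs. The latter was 85.33 with a pseudocount of 0.1. Over all its bins with reads the percentiles were 97.13 and 28.2.

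By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the list alone, the log2 change was -2.80 (SE 0.31, adjusted p = 0.00102) for 42AB and -2.71 (SE 0.50, adjusted p = 0.00734) for 38C_b. By the same test it was -1.37 (SE 0.34, adjusted p = 0.0194) for 20A and 1.66 (SE 0.51, adjusted p = 0.0326) for the chromosome 4 cluster, each with the same sign in both pairs. Averaged over the pairs, the median log2 ratio over all bins with reads of the chromosome 4 cluster was -0.081, opposite in sign to the sum. It was 0.072 in the replicate 1 pair and -0.234 in the replicate 2 pair. Over the 6 bins with at least 1 RPKM in each pair, the medians were 1.72 and 2.12. Random bin sets matched on mean RPKM had medians of 0.421 and 0.735. The filter used the mean of the 2 libraries compared, so bins high in shCuff alone could pass it. For 80F on 3L edgeR's log2 change was -1.12 (SE 0.45, edgeR adjusted p = 0.0702), and for 38C_a on 2L -1.60 (SE 0.96, adjusted p = 0.176). For flamenco on X, a cluster active in somatic follicle cells, it was -0.30 (SE 0.32, adjusted p = 0.389). Adjusted over all 4340 features, edgeR's test called 0 of the 7 clusters, with 42AB at an adjusted p of 0.0905 and 4 clusters at an unadjusted p under 0.05. In that wider adjustment edgeR called 1 cluster with TMM factors, 1 with 1-kb bins as companions and 3 without a filter, and DESeq2 called 2. Limma with either pseudocount, edgeR without the term for library set, with any 1 library left out or with totals without the most abundant bin called 0.

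The cluster calls depended on the test. The planned limma test on log2(RPKM + 1) called 0 clusters over the list alone, with 2 at an unadjusted p under 0.05 and 42AB at -0.92 on that scale (adjusted p = 0.173), and with a pseudocount of 0.1 it called 0 again, with 42AB at -2.25 (limma adjusted p = 0.0992). DESeq2 called 4 clusters lower and 1 higher over the list alone. Without the term for library set, edgeR called 42AB alone (-2.93, adjusted p = 0.0327), with 38C_b at -2.83 (adjusted p = 0.102), 20A at -1.16 (adjusted p = 0.259) and the chromosome 4 cluster at 1.64 (adjusted p = 0.259). Fits with 1 library left out, and no term for set, have a lone library in 1 group that is assumed to vary like the 2 of the other, so their p-values rest on the spread of that other group. In these, edgeR's log2 change of 42AB was -3.43 (adjusted p = 0.00106) without shWhite replicate 2 and -2.73 (adjusted p = 0.0270) without shCuff replicate 2. It was -2.16 (edgeR adjusted p = 0.482) without shWhite replicate 1 and -3.16 (adjusted p = 0.0800) without shCuff replicate 1, where the call was lost. The calls of 38C_b, 20A and the chromosome 4 cluster were lost whichever library was left out, with values from -3.34 to -2.05, from -2.26 to -0.54 and from 1.34 to 2.01. Over all alternatives with a test, the list-alone adjusted p of 42AB ranged from 1.37e-16 (edgeR without a filter) to 0.482. Camera with the preset correlation called the bins of 42AB, 38C_b and 20A lower and those of the chromosome 4 cluster higher; with an estimated correlation it called none, with adjusted p = 0.342 for 42AB, 0.412 for 38C_b and 0.414 for 20A and for the chromosome 4 cluster.

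**Figure D2:**
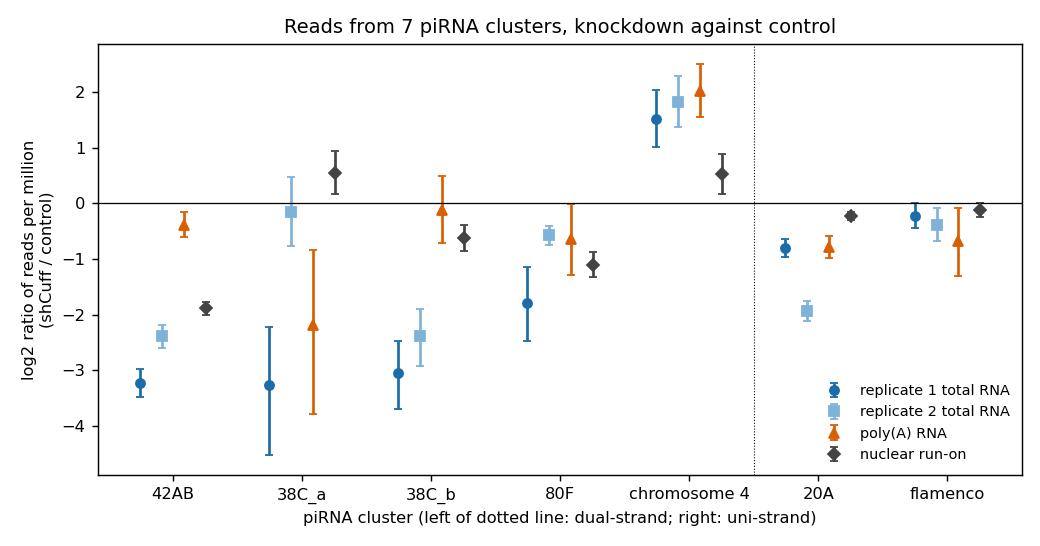
Log2 ratio of RPM, shCuff against control (y axis), for the 7 piRNA clusters (x axis; dual-strand left and uni-strand right of the dotted line), with a point for each of the 4 comparisons. Bars are 95% exact counting intervals. In 42AB all 4 points lie below 0, at ratios of 0.107 and 0.190 in total RNA, 0.765 in poly(A) RNA and 0.271 in run-on.

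Within 42AB the lower level of total RNA extended along the covered part of the locus. Of its 25 sections of up to 10 kb, 18 held at least 10 reads in each total RNA pair. Sections from 2230001 to 2300000 held at most 2 reads per library. Of the 18 sections, 18 were lower in the replicate 1 pair and 16 in the replicate 2 pair. In the replicate 1 pair, 144 of the 243 bins held reads in shWhite and 35 in shCuff, while the number of bins with reads over the whole genome changed by a factor of 0.985. In the replicate 2 pair the number fell from 118 to 18, but there weakly covered regions lost bins beyond their loss of reads: flamenco went from 47 bins to 13 at a read ratio of 0.767, and the right flank of 42AB from 10 to 3 at 1.08. The number of bins in that pair is therefore no measure of the loss in 42AB. The number of lower sections in that pair shares this limit, as shCuff replicate 2 held 0 reads in some of them. An example is the section from 2320001 to 2330000, which went from 68 reads to 0. The left flank of 42AB, 50 kb long, had an edgeR log2 change of -0.07 (SE 0.24), and the right flank, with 6 to 25 reads per library, had -0.24 (SE 0.73). The left flank of 38C had -0.52 (SE 0.29). The right flank of 38C went from 39 reads to 1 in the replicate 1 pair and from 3 to 195 in the replicate 2 pair.

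**Figure D3:**
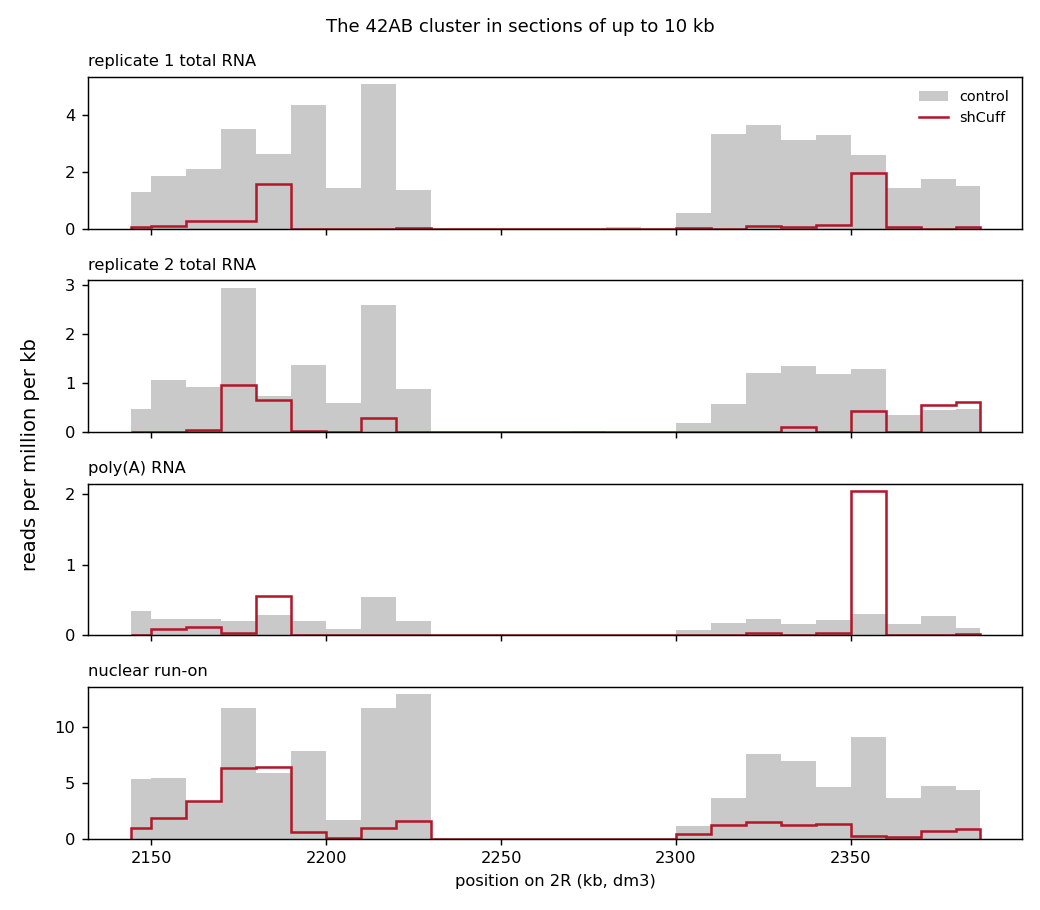
RPM per kb (y axes) along 42AB on 2R (x axis, position in kb, dm3) in sections of up to 10 kb, for the control (grey) and shCuff (red line) in the 4 comparisons. The shCuff line lies below the control in 18 of 18, 16 of 18, 13 of 15 and 17 of 18 sections with at least 10 reads, from top to bottom, and in poly(A) RNA it stands above the control in 2.

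Poly(A) RNA was compared between shWhite and shCuff to follow the polyadenylated part of the same transcripts. Polyadenylated reads from 42AB numbered 324 in each library, or 38.7 RPM in shWhite and 29.6 RPM in shCuff, a ratio of 0.765 (0.654 to 0.895). A single bin, 2R from 2359001 to 2360000, held 7 reads in shWhite and 223 in shCuff. Without it, the ratio of 42AB was 0.244 (0.193 to 0.306), from 317 and 101 reads. Over the whole cluster, 13 of 15 sections were lower. In total RNA the same bin went from 6 reads to 57 and from 0 to 30, and in run-on it held 0 reads in both libraries. The ratio was 0.922 (0.606 to 1.41) for 38C_b, 0.638 (0.408 to 0.991) for 80F, 0.219 (0.0722 to 0.560) for 38C_a and 4.05 (2.93 to 5.70) for the chromosome 4 cluster. The uni-strand clusters had 0.579 (0.505 to 0.664) for 20A and 0.621 (0.405 to 0.946) for flamenco. Genome-wide, 595 of 18680 bins with at least 1 RPKM were at least 2-fold higher in shCuff and 345 were 2-fold lower on the log2(RPKM + 1) scale. None of these differences has a replicate check.

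Nuclear run-on was compared to see whether the difference lay in transcription itself. Reads from 42AB went from 2648 in the control to 738 in shCuff, or from 1086 to 293.8 RPM, a ratio of 0.271 (0.249 to 0.294). Of 18 sections, 17 were lower, and the number of bins with reads went from 128 to 76. The median change of its bins lay at percentile 0 of 10000 random bin sets, and its ratio at percentile 0 of 10000 contiguous windows. The left flank of 42AB also lay at percentile 0 of the random bin sets, with a median of -0.454 against -1.95 in the cluster, but at percentile 25.22 of the contiguous windows. The ratio was 0.465 (0.398 to 0.542) for 80F and 0.646 (0.549 to 0.760) for 38C_b, at percentiles 1.86 and 12.58 of the contiguous windows. The medians over their bins lay at percentiles 4.99 and 0.98 of the random bin sets. Thus 38C_b stood out among bin sets but not among contiguous windows. For the other 4 clusters the percentiles among contiguous windows ran from 43.86 to 69.7. The ratio was 0.854 (0.809 to 0.901) for 20A and 0.918 (0.841 to 1.00) for flamenco. For the chromosome 4 cluster it was 1.44 (1.13 to 1.85), but 0.792 without 1 bin, and for 38C_a it was 1.46 (1.12 to 1.91), but 0.960 without 1 bin. Summed over the dual-strand clusters the ratio was 0.401 (0.378 to 0.426), and over the uni-strand clusters 0.871 (0.832 to 0.912). The reads of 42AB were 2648 of 3760 in the control and 738 of 1553 in shCuff, and the other 4 dual-strand clusters had 0.712 (0.649 to 0.780), from 1112 and 815 reads. The flanks of 42AB had 0.751 on the left and 1.43 on the right. Genome-wide, 13804 of 56298 bins (24.5%) were at least 2-fold higher and 11441 (20.3%) at least 2-fold lower, against 3.19% and 1.85% in the more deeply sequenced poly(A) libraries. These ratios have no replicates, and their control genotype is not that of the RNA libraries.

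The change in poly(A) RNA was set against the change in total RNA of the same set, to ask whether the polyadenylated share of cluster transcripts moved. The log2 ratio of 42AB was larger in poly(A) RNA by 2.84 (2.50 to 3.18), and by 2.94 (2.12 to 3.76) for 38C_b and 1.14 (0.26 to 2.01) for 80F. The intervals of the other dual-strand clusters include 0, with 1.08 (-0.59 to 2.75) for 38C_a and 0.51 (-0.17 to 1.18) for the chromosome 4 cluster. Differences of similar size lay outside the clusters, at 2.23 (0.21 to 4.25) in the right flank of 42AB, from 5 to 19 reads per library, and 2.19 (1.17 to 3.21) at the 2R end. For 20A the difference was 0.02 (-0.24 to 0.27) and for flamenco -0.47 (-1.09 to 0.15). For 42AB the difference includes the bin at 2359001, which raised the poly(A) log2 ratio from -2.04 to -0.39 and the total RNA log2 ratio from -3.99 to -3.23.

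The change in total RNA of the second set was set against the change in run-on to ask whether RNA levels moved beyond transcription. The log2 ratio of total RNA minus that of run-on was -1.76 (-2.30 to -1.23) for 38C_b and -1.71 (-1.90 to -1.52) for 20A. The medians over their bins were -0.19 and -0.40 with a pseudocount of 1 RPKM, at percentiles 49.05 and 12.25 of the random bin sets, but -2.52 and -1.96 with a pseudocount of 0.1, at percentiles 1.22 and 0. The summed difference was 0.53 (0.25 to 0.81) for 80F and 1.29 (0.72 to 1.85) for the chromosome 4 cluster, with medians over bins of 0.32 and 1.75 with a pseudocount of 1 and of -0.18 and 2.52 with a pseudocount of 0.1. These medians of 80F and the chromosome 4 cluster lay at percentiles 97.72 and 98.125 of the random bin sets with a pseudocount of 1. With a pseudocount of 0.1 they lay at 90.29 and 96.21. Among contiguous windows, though, the summed differences of 80F and the chromosome 4 cluster lay at percentiles 62.66 and 51.73. Neither sum stood out there, while those of 38C_b and 20A lay at 3.52 and 1.05. The summed difference was -0.70 (-1.39 to -0.003) for 38C_a and -0.26 (-0.57 to 0.05) for flamenco, at percentiles 20.17 and 29.44. For 42AB the summed reads gave -0.51 (-0.74 to -0.28) and the median over bins 0.72 with a pseudocount of 1 but -0.68 with a pseudocount of 0.1, so no direction is given from the bins. The total RNA side of each difference rests on shCuff replicate 2, the library with few bins of 1 to 3 reads. The controls differ as well, shWhite for total RNA and the driver alone for run-on. A change in RNA level beyond transcription thus cannot be told apart from an effect of the control genotype. An interval on X from 2684001 to 2691000, taken from background knowledge as the place of white, had a difference of 3.25 (2.91 to 3.59).

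Over all 1-kb bins of total RNA, 21 rose and 8 fell among 27388 tested by edgeR, and 1264 had an unadjusted p under 0.05. Of the 21 that rose, 12 (57.1%) lay on heterochromatic or unplaced scaffolds, which held 493 (1.80%) of the bins tested (two-sided Fisher's exact test p = 2.57e-16, with adjacent bins counted as independent). None of the 8 that fell lay there. Of the bins that rose, 20 of 21 had the same sign in both pairs, 19 were at least 2-fold higher in poly(A) RNA and 15 in run-on. All 8 that fell were at least 2-fold lower in both poly(A) RNA and run-on. The test favours bins on which the pairs agree, so the shared sign is no separate support. The exception, Uextra:9061001, held 0 reads in both replicate 2 libraries. Poly(A) RNA is of the same set as the replicate 1 pair, and their log2 ratios in 10-kb windows correlated at a Pearson r of 0.705. The poly(A) counts are thus not independent of the test. A bin that rose on X, from 2685001 to 2686000, had a log2 change of 2.67 in total RNA but -0.97 in run-on and was singled out after its values were seen. It lies in an interval taken from background knowledge as the place of white, the target of the control hairpin, so its rise cannot be assigned to cuff. The bin 3RHet:2183001 went from 0 reads to 88 in the replicate 1 pair and from 0 to 259 in the replicate 2 pair. The bin Uextra:1338001 went from 4 to 820 and from 0 to 147 reads (edgeR log2 change 8.03, SE 0.77, adjusted p = 4.24e-07). In run-on, Uextra:1338001 held 0 reads in both libraries, while 3RHet:2183001 went from 3 to 373. Among those that fell, 2R:20183001 went from 134 to 5 and from 108 to 0 reads (edgeR log2 change -5.79, SE 0.97, adjusted p = 0.00289), and 2L:2244001 from 325 to 42 and from 224 to 8 (edgeR log2 change -3.82, SE 0.64, adjusted p = 0.00289).

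The number and direction of changed bins moved with the method. DESeq2 called 17 higher and 11 lower, of which 15 and 8 were among the 21 and 8, and limma on log2(RPKM + 1) called 37 and 63, of which 17 and 8 were. With TMM factors edgeR called 4 higher and 0 lower, with 951 bins at an unadjusted p under 0.05. Without the term for library set edgeR called 0, with 105 at an unadjusted p under 0.05. With 1 library left out it called 0 higher and 0 lower without shWhite replicate 1 or shWhite replicate 2, 3 and 12 without shCuff replicate 1, and 5 and 2 without shCuff replicate 2. At an unadjusted p under 0.05, those 4 fits had 195, 538, 2613 and 428 bins. In 10-kb windows, the log2 ratios of the replicate pairs correlated at a Pearson r of 0.26 over 4232 windows, which are not independent replicates.

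Chromosome classes were compared because piRNA clusters lie next to repeat-rich sequence. The unplaced scaffold set Uextra had a higher share of reads in shCuff in each comparison, with ratios of 2.005 and 6.75 in the total RNA pairs, 3.87 in poly(A) RNA and 2.67 in run-on. Its log2 change in total RNA was 1.87 (SE 0.50), which did not pass (edgeR adjusted p = 0.0787 over the classes alone). Of Uextra bins with at least 1 RPKM, 42.4% and 87.3% were at least 2-fold higher in the total RNA pairs, 62.2% in poly(A) RNA and 59.8% in run-on. On the main arms those shares were 9.82%, 29.4%, 2.74% and 23.7%. The Uextra shares rest on 172, 55, 74 and 443 of 29005 bins. The filter used the mean of the 2 libraries compared, so bins high in shCuff alone could pass it. Over all Uextra bins, 616 were higher and 513 lower in the replicate 1 pair, but 132 higher and 181 lower in the replicate 2 pair. In poly(A) RNA 780 were higher and 317 lower, and in run-on 610 and 387. Heterochromatic scaffolds had ratios of 1.13 and 0.993 in total RNA, 1.10 in poly(A) RNA and 1.44 in run-on. The mitochondrial genome had 1.02 in the replicate 1 pair but 0.319 in the replicate 2 pair, 0.824 in poly(A) RNA and 1.38 in run-on, and its total RNA change did not pass (edgeR adjusted p = 0.558 over the classes alone).

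**Figure D4:**
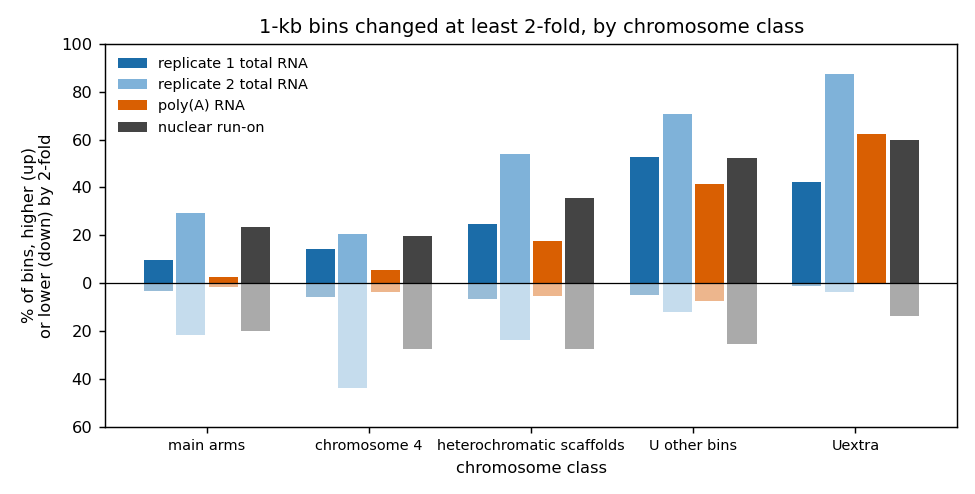
Percent of 1-kb bins with at least 1 RPKM that were at least 2-fold higher (bars up) or lower (pale bars down) in shCuff, by chromosome class (x axis), for the 4 comparisons. In Uextra the bars up reach 42.4%, 87.3%, 62.2% and 59.8%, and the bars down stay at or below 13.5%. These are shares of the 172, 55, 74 and 443 Uextra bins that passed this filter.

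The ends of the chromosome arms, where telomeric retrotransposons lie, did not move alike. The 2R end had ratios of 0.844 (0.470 to 1.496) and 7.37 (5.08 to 11.05) in the total RNA pairs, 3.86 (2.43 to 6.41) in poly(A) RNA and 2.79 (2.04 to 3.86) in run-on, with an edgeR log2 change of 1.38 (SE 0.95) in total RNA. The 3L end held 0 reads in all of its 20 bins in every library, run-on included. Counting alone allows up to 0.274 to 1.23 RPM. Whether reads could be placed in that sequence was not analysed here, so no level is given for it. The X end had 0.990 and 0.937 in total RNA, 0.911 in poly(A) RNA and 15.4 in run-on. In the total RNA pairs, the 2L end had 1.32 and 0.404 and the 3R end 1.41 and 0.464, and in run-on these ends had 0.962 and 1.02.

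A scan for longer stretches, set up after the data had been seen, asked which 30-kb windows changed at least 3-fold in both total RNA pairs and in run-on. Windows that passed merged into 12 lower and 23 higher stretches among 7100 windows. Of the lower ones 2 lay in 42AB and 6 on heterochromatic or unplaced scaffolds, and of the higher ones 1 lay in the chromosome 4 cluster and 14 on such scaffolds. A lower stretch outside the clusters, on chromosome 4 from 810001 to 870000, went from 172 reads to 6 in the replicate 1 pair, a ratio of 0.0397 (0.0144 to 0.0882). It was 0.173 (0.116 to 0.253) in the replicate 2 pair, 0.0407 (0.0129 to 0.0984) in poly(A) RNA and 0.0670 (0.0510 to 0.0865) in run-on, where reads went from 913 to 63. The 10 kb on its left and the 10 kb on its right had ratios of 1.09 and 1.19 in run-on and 2.13 and 1.71 in the replicate 1 pair. In poly(A) RNA they had 2.05 and 1.56. They had 0.358 and 0.301 in the replicate 2 pair, where the neighbours were thus lower too.

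**Figure D5:**
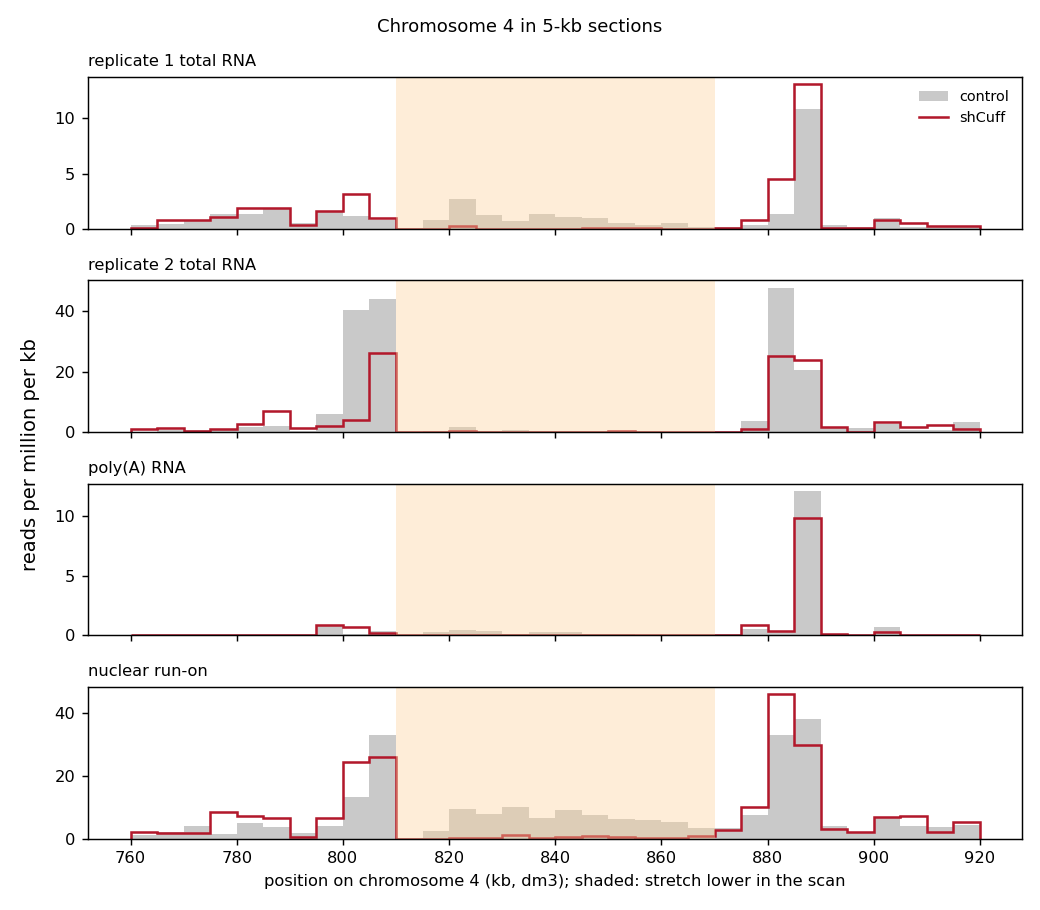
RPM per kb (y axes) on chromosome 4 (x axis, position in kb, dm3) in 5-kb sections, for the control (grey) and shCuff (red line) in the 4 comparisons, with the stretch from 810001 to 870000 shaded. Within the shading, run-on held 374.4 RPM in the control and 25.1 RPM in shCuff.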

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

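All tests in this part were chosen after the results had been seen, and they were revised after a first run.

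A difference between run-on and total RNA was noted for 3 regions because the run-on ratio lay on the other side of 1 from both total RNA ratios; none of these differences was tested, and run-on had another control genotype. The cluster 38C_a had a run-on ratio of 1.46, but 0.960 without 1 bin, against 0.103 and 0.901 (0.587 to 1.39) in the total RNA pairs. All 50 reads of shCuff replicate 2 in that cluster lay in 1 bin, and without it the ratio of 0.901 became 0. The X end had a run-on ratio of 15.4, from 47 reads in the control to 747 in shCuff. Its total RNA ratios of 0.990 (0.959 to 1.02) and 0.937 (0.876 to 1.003) had intervals that include 1. An interval on X from 2684001 to 2691000, taken from background knowledge of dm3 as the place of white and not checked against an annotation, had a run-on ratio of 0.722. There the total RNA ratios were 3.89 and 6.85 and the poly(A) ratio 4.10, all against a control whose hairpin targets white, whereas the run-on control carried no hairpin. In the scaffold YHet, outside the comparisons, the shCuff run-on library held 14 reads and its control 0, while the other 6 libraries held 0 or 1.

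Few bins of shCuff replicate 2 of total RNA held a low number of reads, 8.37% with 1 to 3, and the most frequent count from 5 upwards was 16. The other 3 shCuff libraries had at least 30.2% of their bins with reads at 1 to 3, which argues against an effect of the knockdown on RNA in general. Repeated reads of few molecules may have produced the pattern, but the test required 40% or more in each other total RNA library, and shWhite replicate 2 had 35.7%. That bound, set after the data were seen, was not moved, so the test left this explanation open. Another value goes with it. Among bins with low mean coverage in the other libraries, those with reads held a median of 16 in shCuff replicate 2. In the other total RNA libraries this median was 1, 1 and 2. It was 2 in each poly(A) library, and 10 in shCuff and 5 in the control of run-on. Repeated reads were not counted directly. The pattern bears on every value of the replicate 2 pair, and 42AB was lower without that library too (ratio 0.107 in the replicate 1 pair).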

How the results depend on the processing

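The tests with DESeq2, with 1 library left out, with totals without the most abundant bin, with 1 bin left out of a cluster and with other fold thresholds of the scan were chosen after the data had been seen; the other alternatives were planned. In total RNA, the signs of the summed changes of 42AB, 38C_b, 20A and the chromosome 4 cluster were kept in every alternative run. Calls were lost in some settings and kept in others. Clusters that fell numbered 3, and 3 to 4 with TMM factors, no filter, DESeq2, 1-kb bins as companions and totals without the most abundant bin, but 1 with no replicate block, 0 with limma at either pseudocount and 0 to 1 with a library left out. The call of the chromosome 4 cluster was lost in each of the latter settings, giving 0. Without the block the call of 42AB was kept. Bins that rose numbered 21, but 0 with no replicate block, 4 with TMM factors, 41 without a filter, 37 and 40 with limma at pseudocounts of 1 and 0.1, 0 to 5 with a library left out and 10 with totals without the most abundant bin. Bins that fell numbered 8, but 0, 0, 18, 63, 136, 0 to 12 and 0 in the same order. More bins were tested without a filter (62580), and fits with a library left out had fewer samples and no term for set; for the other settings the cause was not tested.

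Some directions reversed. For 80F, whose change did not pass, leaving out a library gave -2.96 to 0.42, with 0.06 without shCuff replicate 1 and 0.42 without shWhite replicate 2. For flamenco it gave -1.45 to 0.80, with 0.80 without shWhite replicate 1 and 0.39 without shCuff replicate 2. The median over all bins with reads of the chromosome 4 cluster, averaged over the pairs, was -0.081, but it was 0.072 in the replicate 1 pair. In run-on, leaving out 1 bin turned 38C_a to -0.060 and the chromosome 4 cluster to -0.34. The fits with a library left out had no term for set, so level differences between the sets entered them. In shWhite these levels were 29.2 and 103.0 RPM for 80F and 112.6 and 35.3 RPM for flamenco. Within each pair shCuff was lower, with log2 ratios of -1.78 and -0.57 for 80F and -0.22 and -0.38 for flamenco. Those reversals therefore give no direction for either cluster. In the run-on reversals a single bin made the difference. For the median over bins the cause was not tested.

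Poly(A) bins at least 2-fold higher and lower numbered 1198 and 610 with a pseudocount of 0.1, which by construction shrinks small values less. The percentile of 42AB for poly(A) against total RNA was 99.45 among contiguous windows; the value of 100 among bin sets carries little weight, since poly(A) bins of 42AB lie near the floor (0.159 RPKM per bin in shWhite). For total RNA against run-on it was 100 but 67.24 with a pseudocount of 0.1 and 13.18 among contiguous windows, and the cause was not tested. At 2-fold the scan gave 22 lower and 38 higher stretches. Of the remaining values for single clusters and classes, 108 stayed within their threshold or interval, 60 moved, 25 lost a call and 2 gained one. The planned gene-level alternatives were not run because no dm3 annotation was used. Each pair alone gives values but no count of calls, and for poly(A) RNA 42AB had too few bins at 1 RPKM for a percentile among bin sets. Depth limits clusters such as 38C_a, with 8 to 88 reads in total RNA, most.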

Other observations

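All tests in this part were chosen after the results had been seen. The scan that found the stretches below followed a first look with other settings, in which the stretch on chromosome 4 was already known.

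Several heterochromatic stretches had more reads in shCuff in all 4 comparisons. The scan required a change of at least 3-fold in both total RNA pairs and in run-on, so that agreement was fixed by the selection. Poly(A) RNA is of the same set as the replicate 1 pair and is no independent check. On 3RHet from 2100001 to 2210000 the ratios were 12.0 and 36.9 in the total RNA pairs, 29.0 in poly(A) RNA and 30.02 in run-on, where reads went from 163 to 5040. On 3RHet from 550001 to 710000 they were 10.4, 20.8, 18.3 and 17.998. In poly(A) RNA that rise was uneven, with 2524 of the 4807 shCuff reads in the bin 3RHet:641001. On the log2(RPM + 1) scale, the 10-kb windows at 570001 and 640001 had poly(A) changes of 4.04 and 4.23. Those at 600001 and 630001 had 0.04 and 0.14. Other stretches had fewer reads. On 2RHet from 1670001 to 1730000 the ratios were 0.0278 and 0.0180 in total RNA, 0.106 in poly(A) RNA and 0.132 in run-on. Run-on reads there went from 125 to 17. In the left end of 3RHet, from 1 to 40000, the 29 and 30 reads of the total RNA controls went to 0 in both shCuff libraries. Which repeats lie there was not analysed here, and the placement of repeated reads limits these values.

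The loss of reads over 60 kb of chromosome 4, from 810001 to 870000, was seen in all 4 comparisons. Of 1326 other stretches of that length, 3 were at least 4-fold lower in both the replicate 1 pair and run-on. As the stretch was selected on those comparisons, this count gives a background and does not test it. The scan required fewer reads in both total RNA pairs and in run-on. It did not use the unreplicated poly(A) pair, whose ratio had an upper limit of 0.0984. That pair is of the same set as the replicate 1 pair, though. In 10-kb windows the log2 ratios of these pairs correlated at a Pearson r of 0.705, so its loss is no independent test. A variant carried by the hairpin parent on 1 of 2 copies and acting on its own copy would leave at least 0.5. The poly(A) limit lay below that, but as the pair depends on the selection, no conclusion is drawn on such a variant. The loss in the poly(A) pair cannot come from repeated reads in shCuff replicate 2, a library outside that pair. Knockdown of cuff could account for the loss. The 10 kb on either side were not lower in poly(A) RNA, at 2.05 and 1.56. They were lower in the replicate 2 pair, though, the lowest at 0.301, so the test did not decide. With 1 hairpin line the effects of Cutoff and of that line's background cannot be told apart here.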
